A study of Salmo salar with 72 samples.

How the data were processed

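The measurements were RNA-seq libraries of primary hepatocytes from 6 male Atlantic salmon, grown on porous 3-dimensional scaffolds and exposed for 48 h to arsenite (AsIII), arsenate (AsV) or arsenobetaine (AsB). The 72 libraries fell into 14 groups by compound and nominal dose, each compound with its own control group, as the sample titles give them. AsIII (30 libraries, doses of 3, 10, 30 and 100 µM) and AsB (30 libraries, doses of 10, 50, 100 and 500 µM) were tested in cells of all 6 fish, and AsV (12 libraries, doses of 10, 50 and 100 µM) in cells of fish 1 to 3. Each library is 1 culture of 1 fish, so the spread between replicates is the spread between animals.

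Reads were aligned with HISAT2 and counted per gene with featureCounts of the Subread package, per the submitters' processing notes, which give no version of either. The same notes name DESeq2 1.40.2. The deposited values are a normalized signal, that is read counts per gene divided by a size factor per library, by the authors. The genome build and the treatment of reads that match several places are not given in the sources used here, and no coordinates are printed. The table held 25830 genes, each at a value of 10 or more in at least 10 libraries. All of its columns belonged to 1 of the 72 libraries.

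The low values of each library were whole multiples of what 1 read was worth, and dividing by that step gave whole reads for 100% of the values in the library with the lowest share (tolerance 0.01 of a read). Recovered depths ran from 30.9 to 86.4 M reads per library, with a median of 38.6 M. Size factors ran from 0.658 to 1.78. The tests fixed before the data were examined assumed raw read counts and edgeR. Because the deposited values were normalized, the main test became limma on log2(value + 1), and count tests on the recovered reads were added as alternatives. Fold changes are therefore on the log2(value + 1) scale, which understates the change of genes with low values.

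Genes were kept where the value was 10 or more in at least as many libraries as the smallest group of the fit held. For each compound, a linear model with a mean per group was fitted across its libraries with limma 3.58.1 in R 4.3.3, with an intensity trend and robust empirical Bayes variances. Differences between the responses to 2 compounds at a matched dose, and differences between control groups, came from a fit over all 72 libraries. Changes carry their standard error (SE), and p-values are 2-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The design covers 24 such comparisons, namely 11 of a dose with its control, 3 of neighbouring AsIII doses, 7 of responses and 3 of controls. Doses of a compound share their control libraries, so genes and lists were tested between AsIII doses only through the test of the difference. Counts of calls, sizes of change and correlations at different AsIII doses are also set side by side below, and these share the controls.

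The same fish number in different groups stands for the same animal, so the numbers pair the libraries. On average, libraries of the same fish deviated together from their group means. The mean correlation across 19394 genes was 0.440 for AsIII, 0.230 for AsV and 0.240 for AsB. Between different fish it was -0.109, -0.209 and -0.0761, where removing the group means by itself makes values negative. Single same-fish values ran from -0.211 to 0.530 for AsV, and the lowest were 0.216 for AsIII and 0.106 for AsB. The main fits carry no fish term, as fixed before the data were examined. A fit with the fish as a block is printed beside a result where it changes the call or moves a count by more than 1.5 times. Within groups, no 2 libraries were copies of each other. Over 162 pairs of libraries within groups, the lowest chi-square per gene was 19.2. Libraries of different groups, among them those of the same fish, were not compared in this way.

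Gene names came from the deposited table and from a reference gene table, which matched 23011 of the 25830 genes. Most symbols (20080) were of the LOC type, and 179 genes had a symbol used more than once and were kept apart by their gene number. The salmon genome holds many near-identical gene copies, and values of such copies are uncertain because reads could be split between them. Before the data were examined, 22 gene lists were fixed: redox defence genes under NRF2, heat shock, metal response, integrated stress and unfolded protein response, p53 and cell death, arsenic and 1-carbon metabolism, proteasome and ubiquitin, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, hepatocyte products, acute phase and inflammation, aryl hydrocarbon receptor targets, carbohydrate metabolism, nuclear genes of oxidative phosphorylation, ribosomal proteins, cell cycle, matrix and cytoskeleton, and markers of erythroid, leukocyte, endothelial and biliary cells. Matching to names ignored isoform, precursor and low-quality tags, and 6 wrong matches were left out before any test. The lists held 1066 genes. Lists were tested with camera on the log2(value + 1) scale with a preset correlation of 0.01 between genes, with an estimated correlation and with fry as alternatives. All values with an estimated correlation or with fry come from fits without the fish block. Lists called with the block only were therefore not checked with the block and an estimated correlation together. Camera asks whether genes of a list rank higher or lower than other genes. The p-values of lists were adjusted within families, the comparisons of doses with controls making 242 tests.

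Genes named in the text followed a rule fixed before the data were examined. It takes all 36 copies of 14 stress and liver genes (hmox1, mta, mtb, hsp70, gclc, gclm, sqstm1, txnrd1, as3mt, atf3, ddit3, cyp1a, alb1 and alb2). It also takes the genes with the greatest rise and fall among those past the threshold, with a name, with a mean of log2(CPM + 0.5) of at least 1 and with the same sign in every fish, and up to 4 members per list with the greatest change past the threshold. Genes called uncharacterized or hypothetical were passed over among the greatest changes. The 13 mitochondrially encoded mRNAs are reported as a set. Any other gene is named as chosen after its values were seen.

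Alternatives were DESeq2 1.42.0 and edgeR 4.0.16 on the recovered reads with the same gene filter, TMM or library-size scaling, pseudocounts of 0.5 and 10, other filters on low values, the fish block, fits over fewer or more libraries, a threshold of 1 on the absolute log2 fold change, and leaving out each fish in turn. Other groupings of the same libraries, at most 100 per comparison, were run through the same test. The procedure was tested on simulated reads in which 200 genes were changed by known folds. It recovered 48% of the 2-fold and 76% of the 4-fold changes in a simulation of AsIII at 3 µM (25298 genes), 24% and 66% in one of AsV at 10 µM (25064 genes), and 47% and 79% in one of AsB at 500 µM (25277 genes). The simulated libraries were independent, with no fish effect and with 1 spread per gene taken from all 72 libraries. These shares therefore do not compare the power of the real AsIII and AsB tests, whose median 95% intervals reached 0.43 and 0.64 to either side. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The label texts conflict. The free-text description of every library names arsenosugar and arsenite as the compounds, and the treatment protocol gives arsenite doses up to 30 µM. Titles and treatment fields name AsIII, AsV and AsB and AsIII doses up to 100 µM, and the extraction protocol names these 3 compounds. The groups follow the titles, and the conflict, which bears on what the AsB and the AsIII values stand for, was not settled.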

Results

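Hepatocytes isolated from 6 Atlantic salmon were exposed in parallel to 3 arsenic compounds for 48 h, and their mRNA was sequenced. Arsenite (AsIII) and arsenate (AsV) are the trivalent and pentavalent inorganic oxyanions, and arsenobetaine (AsB) is the methylated organic form that prevails in marine fish. The comparisons ask which genes respond to each compound, at which dose, and whether the responses differ between compounds. Compounds and doses are those of the sample titles, with which other label texts conflict. Groups held 6 libraries for AsIII and AsB and 3 libraries for AsV. Library depth was 30.9 to 86.4 M reads for AsIII, 31.8 to 48.3 M for AsV and 32.7 to 68.4 M for AsB. The number of the 25830 genes listed at 0 differed between the compounds' libraries, with a median of 208.5 for AsIII, 249.5 for AsV and 1608 for AsB. Changes below are log2 fold changes ± SE against the control of the same compound, and levels are normalized read counts ± SD. Counts of list members are over all genes tested, and counts adjusted over the list alone are given where they differ.

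At 3 µM AsIII, the genes that rose included members of the heat shock, integrated stress and redox lists. The stress-inducible hsp70 copy LOC106572869 stood at 12333 ± 2752 normalized counts against 29.5 ± 38.4 in the controls (n = 6). Its log2 change was 9.84 ± 0.63 (adjusted p = 5.63e-13). The heat shock protein beta-11-like gene LOC106563467 rose by 10.11 ± 0.64, the co-chaperone bag3 by 7.60 ± 0.20 and polyubiquitin ubc by 4.04 ± 0.13. The autophagy receptor sqstm1 rose by 3.88 ± 0.14 to 788783 ± 54525 normalized counts, and the heme oxygenase copy LOC106590330 rose by 3.15 ± 0.22. All of these were higher in 6 of 6 fish. The greatest falls were those of the pseudokinase fam20a (-4.24 ± 0.96), the Wnt-9a-like gene LOC106599874 (-4.24 ± 0.66), the vitamin D 24-hydroxylase-like gene LOC106583685 (-3.84 ± 0.28) and fastkd5 (-3.82 ± 0.26), a gene of mitochondrial RNA processing.

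Of 60 heat shock genes, 49 rose and 3 fell at 3 µM (50 and 3 adjusted over the list alone). Their median was 2.96 and the camera adjusted p was 2.94e-20 (adjusted p = 0.103 with an estimated correlation). Of 63 genes of the integrated stress and unfolded protein response, 45 rose and 7 fell (47 and 7 adjusted over the list alone, camera adjusted p = 1.6e-08, adjusted p = 0.393 with an estimated correlation). They included the ppp1r15a-like gene LOC106561078 (4.77 ± 0.29), which acts in the reversal of eIF2α phosphorylation, and both ddit3 copies (3.21 ± 0.21 and 2.41 ± 0.14). Of 67 redox genes, 34 rose and 11 fell, among them nf2l2, which encodes NRF2 (3.00 ± 0.11), and the glutathione synthesis gene gsh0 (1.86 ± 0.15). The camera adjusted p of this list was 0.0286 (adjusted p = 0.827 with an estimated correlation), and its median of 0.38 was 0.12 under library-size scaling. The p53 and cell death list had 29 rises and 11 falls of 49 genes (30 and 11 adjusted over the list alone, camera adjusted p = 0.000776, adjusted p = 0.446 with an estimated correlation). Among the rises were the cyclin-dependent kinase inhibitor 1-like gene LOC106576064 (4.58 ± 0.20) and the ddit4-like gene LOC106577395 (5.18 ± 0.47). Nuclear genes of oxidative phosphorylation went the other way. They gave 62 falls and 2 rises of 134 (median -0.27, camera adjusted p = 4.55e-05, adjusted p = 0.996 with an estimated correlation). Proteasome and ubiquitin genes gave 29 rises and 8 falls of 69, and acute phase and inflammation genes 19 and 5 of 44. Both lists were called with the fish block only (camera adjusted p = 0.0566 and 0.0531, 0.0278 and 0.019 with the block, and adjusted p = 0.996 and 0.951 with an estimated correlation). Of 181 ribosomal protein genes, 6 fell and 1 rose (3 and 1 adjusted over the list alone), again called with the block only (camera adjusted p = 0.0839, 0.0362 with the block, and adjusted p = 0.996 with an estimated correlation). Mitochondrial mRNA made up 2.27% ± 0.340 of reads at this dose and 2.76% ± 0.306 in the controls. Of the 13 mitochondrially encoded genes, 6 fell (7 with the fish block), among them ND4L (-1.37 ± 0.34) and ND3 (-1.16 ± 0.26).

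The 2 cyp1a copies, which encode a xenobiotic-metabolizing cytochrome P450, fell by 1.26 ± 0.19 and 2.02 ± 0.37 at 3 µM. The 34 targets of the aryl hydrocarbon receptor gave 10 rises and 4 falls (9 and 4 adjusted over the list alone) and were not called as a list (camera adjusted p = 0.36). Of the 4 copies annotated as the arsenic methyltransferase as3mt, LOC106568062 rose (1.03 ± 0.30), while as3mt (-0.45 ± 0.15), LOC106581028 (-0.53 ± 0.10) and LOC106588782 (-0.52 ± 0.07) fell. The metallothionein gene mtb (LOC100136581) changed by 0.69 ± 0.33 and mta (LOC100136589) by 0.25 ± 0.45, neither past the threshold without the fish block (adjusted p = 1.91e-06 for mtb and 0.0355 for mta with it). In total 7621 genes rose and 6453 fell of 25801 tested with limma. Under library-size scaling the median of all genes was -0.21 and the split became 5643 rises and 9296 falls, with albumin copies alb1 and LOC100136922, which rose by 0.24 ± 0.10 and 0.25 ± 0.11, turning to -0.03 and -0.01.

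At 10 µM AsIII, the genes that rose included members of the heat shock, integrated stress and cholesterol synthesis lists. LOC106572869 rose by 9.49 ± 0.63, the glutathione-degrading enzyme gene chac1 by 5.23 ± 0.14 and the amino acid transporter subunit slc3a2 by 4.85 ± 0.21, whereas sestrin sesn1 fell (-3.42 ± 0.24). Of 63 integrated stress genes, 50 rose and 3 fell (50 and 4 adjusted over the list alone, camera adjusted p = 1.78e-15, adjusted p = 0.101 with an estimated correlation). Of 60 heat shock genes 43 rose and 0 fell (44 and 0 adjusted over the list alone, camera adjusted p = 1.95e-22, adjusted p = 0.101 with an estimated correlation). Among 35 cholesterol synthesis genes, 24 rose and 3 fell (25 and 3 adjusted over the list alone, camera adjusted p = 0.00303, adjusted p = 0.996 with an estimated correlation). They included mevalonate kinase mvk (2.03 ± 0.32) and the HMG-CoA synthase-like gene LOC106571543 (2.10 ± 0.28). Of 44 acute phase and inflammation genes 30 rose and 4 fell (32 and 4 adjusted over the list alone, camera adjusted p = 4.55e-05, adjusted p = 0.223 with an estimated correlation). The list was led by the jun-B-like gene LOC106607038 (4.36 ± 0.28). Of 49 p53 and cell death genes, 31 rose and 8 fell (camera adjusted p = 0.000226, adjusted p = 0.393 with an estimated correlation). The 181 ribosomal protein genes gave 69 rises and 2 falls (49 and 2 adjusted over the list alone, camera adjusted p = 0.000629, adjusted p = 0.996 with an estimated correlation). Their median of 0.21 became -0.10 under library-size scaling. Of 69 proteasome and ubiquitin genes, 29 fell and 10 rose (30 and 10 adjusted over the list alone). Their median was -0.29 and their mean 0.01, and the list was called with the block only (camera adjusted p = 0.0531, 0.0101 with the block, and adjusted p = 0.996 with an estimated correlation). In the metal response list, 9 of 19 genes fell and 1 rose (median -0.34, camera adjusted p = 0.046, adjusted p = 0.363 with an estimated correlation). Of the 13 mitochondrial genes, 8 fell (9 fell and 1 rose with the fish block), among them ND3 (-1.43 ± 0.26) and ND1 (-1.25 ± 0.23). The dose gave 6906 rises and 5283 falls with limma, against 4366 and 9072 under library-size scaling, where the median of all genes was -0.24.

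At 30 and 100 µM AsIII, the genes that rose included members of the acute phase and inflammation list, and those that fell included proteasome and mitochondrially encoded genes. The tissue factor-like gene LOC106568893, which encodes a starter of blood coagulation, rose by 6.37 ± 0.55 at 30 µM and 5.21 ± 0.55 at 100 µM. The ATF3-like gene LOC106607825 rose by 4.93 ± 0.14 and 3.39 ± 0.14, and LOC106561078 by 6.50 ± 0.29 and 4.57 ± 0.29. The egg-yolk precursor vitellogenin (LOC100136426) fell by 3.55 ± 0.62 and 3.58 ± 0.62, from 487436 ± 209587 normalized counts in the controls to 49974 ± 41816 at 100 µM, and was lower in 6 of 6 fish. Mitochondrial mRNA made up 0.656% ± 0.181 of reads at 30 µM and 0.652% ± 0.224 at 100 µM. At 100 µM, 12 of the 13 mitochondrial genes were past the threshold and lower, with ND2 at -3.12 ± 0.22, ND1 at -3.04 ± 0.23 and COX2 at -2.85 ± 0.19, and ATP6 at -0.33 ± 0.17 passed it with the fish block only (adjusted p = 0.125, and 0.0014 with the block). The 134 nuclear oxidative phosphorylation genes gave 31 falls and 13 rises at 30 µM (24 and 9 adjusted over the list alone, camera adjusted p = 0.0291, adjusted p = 0.996 with an estimated correlation). At 100 µM 32 fell and 12 rose (28 and 12 adjusted over the list alone, median -0.15, camera adjusted p = 0.0112, adjusted p = 0.996 with an estimated correlation).

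Of 69 proteasome and ubiquitin genes, 42 fell and 8 rose at 30 µM (camera adjusted p = 4.47e-08, adjusted p = 0.763 with an estimated correlation). At 100 µM 44 fell and 4 rose (median -0.61, camera adjusted p = 4.31e-13, adjusted p = 0.412 with an estimated correlation). Among them psmd5, a proteasome assembly factor, fell by 1.22 ± 0.10 and 1.4 ± 0.10. Cholesterol synthesis genes gave 24 rises and 2 falls at 30 µM and 20 and 1 at 100 µM, of 35 (25 and 24 rises adjusted over the list alone, camera adjusted p = 7.9e-05 and 0.000404, adjusted p = 0.996 with an estimated correlation at both). The acyl-CoA desaturase-like gene LOC106577210 fell by 1.77 ± 0.14 and 1.74 ± 0.14 and elovl6 by 1.63 ± 0.25 and 1.58 ± 0.25. Both act in fatty acid synthesis, a list of 28 genes with 7 falls and 5 rises at 30 µM and 11 and 3 at 100 µM. It was called at 100 µM with the block only (camera adjusted p = 0.0621, 0.0268 with the block, and adjusted p = 0.996 with an estimated correlation). The 44 acute phase genes gave 28 rises and 2 falls at 30 µM and 30 and 2 at 100 µM (33 and 2 adjusted over the list alone at 100 µM, camera adjusted p = 5.77e-07 and 4.77e-08, adjusted p = 0.101 with an estimated correlation at both). The heat shock list gave 34 rises and 2 falls at 30 µM (34 and 3 adjusted over the list alone, camera adjusted p = 4.96e-13, adjusted p = 0.363 with an estimated correlation). At 100 µM it gave 26 and 6 (27 and 6 adjusted over the list alone, camera adjusted p = 0.000152, adjusted p = 0.978 with an estimated correlation). Erythroid markers were near the floor, with hemoglobin at 0.00062% of reads in the controls. At 100 µM, 4 of 8 erythroid genes fell and 0 rose (limma, 5 falls adjusted over the list alone, median -2.44, camera adjusted p = 0.0392, adjusted p = 0.996 with an estimated correlation). Integrated stress genes gave 46 rises and 3 falls of 63 at 30 µM and 38 and 3 at 100 µM (41 and 3 adjusted over the list alone at 100 µM, camera adjusted p = 2.36e-11 and 4.83e-08, adjusted p = 0.223 and 0.412 with an estimated correlation). Of 49 p53 and cell death genes, 25 rose and 3 fell at 30 µM (25 and 4 adjusted over the list alone, camera adjusted p = 0.0026, adjusted p = 0.577 with an estimated correlation). At 100 µM 20 rose and 6 fell (21 and 6 adjusted over the list alone), and the list was called with the block only (camera adjusted p = 0.0529, 0.0308 with the block, and adjusted p = 0.978 with an estimated correlation). The aquaglyceroporin gene aqp9, whose product carries arsenite, rose by 1.10 ± 0.22 and 1.45 ± 0.22.

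The counts at 30 µM were 6170 rises and 4557 falls, or 4902 and 6131 under library-size scaling, and at 100 µM 5831 and 4475, or 5026 and 5466. The 100 µM library of fish 1, with 1694 genes at 0, and the 30 µM library of fish 5, with 1396, stood apart from the rest. Without fish 1 the 100 µM count was 9536, and without fish 5 the 30 µM count was 9295.

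**Figure D1:**
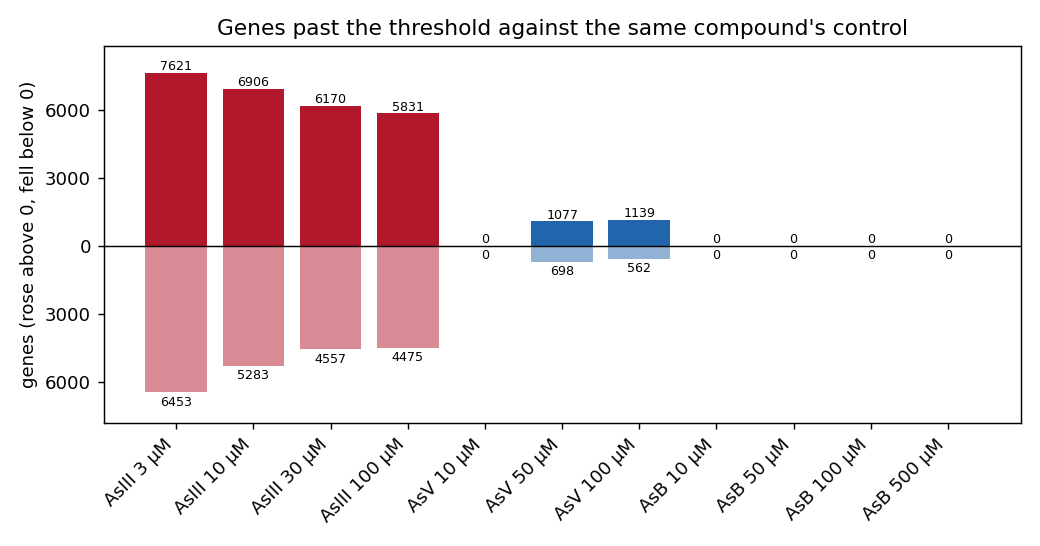
Genes past an adjusted p of 0.05 with limma, by dose group in µM, for AsIII, AsV and AsB, with rises and falls shown apart. AsIII gave 7621 rises at 3 µM and 5831 at 100 µM, AsV gave 0 calls at 10 µM and AsB 0 at every dose.

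Neighbouring AsIII doses were compared with each other. From 3 to 10 µM, 3770 genes rose and 4059 fell. In that step 36 of 69 proteasome genes fell and 2 rose (40 and 7 adjusted over the list alone, adjusted p = 0.538 with an estimated correlation). Over the same step 120 of 181 ribosomal protein genes rose (144 adjusted over the list alone, median 0.27, adjusted p = 0.62 with an estimated correlation). From 10 to 30 µM, 2575 genes rose and 2939 fell (4320 and 1674 under library-size scaling). In this step 36 of 60 heat shock genes fell (39 adjusted over the list alone, median -0.96, adjusted p = 0.0804 with an estimated correlation). From 30 to 100 µM, 38 genes rose and 394 fell, and 904 genes in all were called with the fish block. In this last step 21 of 60 heat shock genes fell and 0 rose (35 and 0 adjusted over the list alone, limma, median -0.78, adjusted p = 0.00619 with an estimated correlation).

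**Figure D2:**
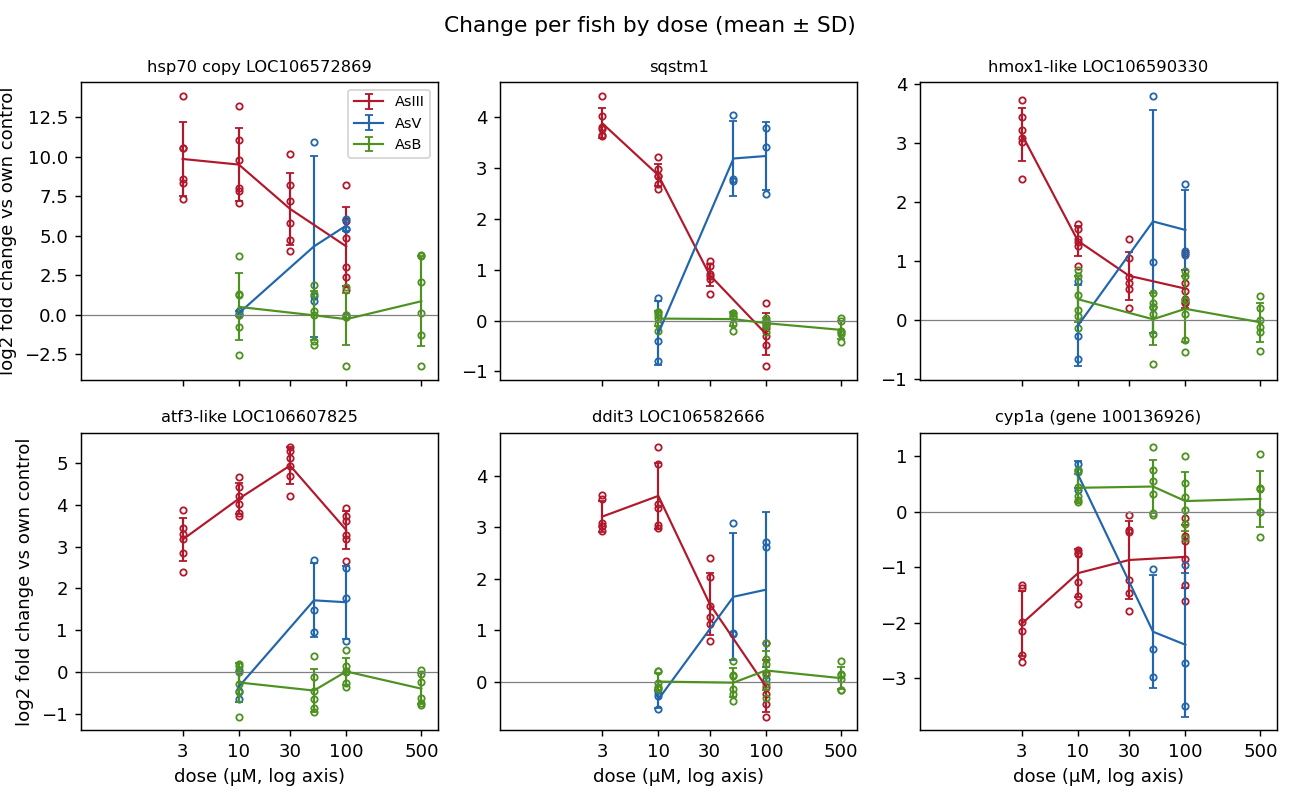
Log2 fold change against the same compound's control, by dose in µM, for stress genes named in the text, with a point per fish and the mean. The hsp70 copy LOC106572869 lay at 9.84 at 3 µM AsIII and 4.32 at 100 µM, and sqstm1 at 3.88 and -0.26.

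**Figure D3:**
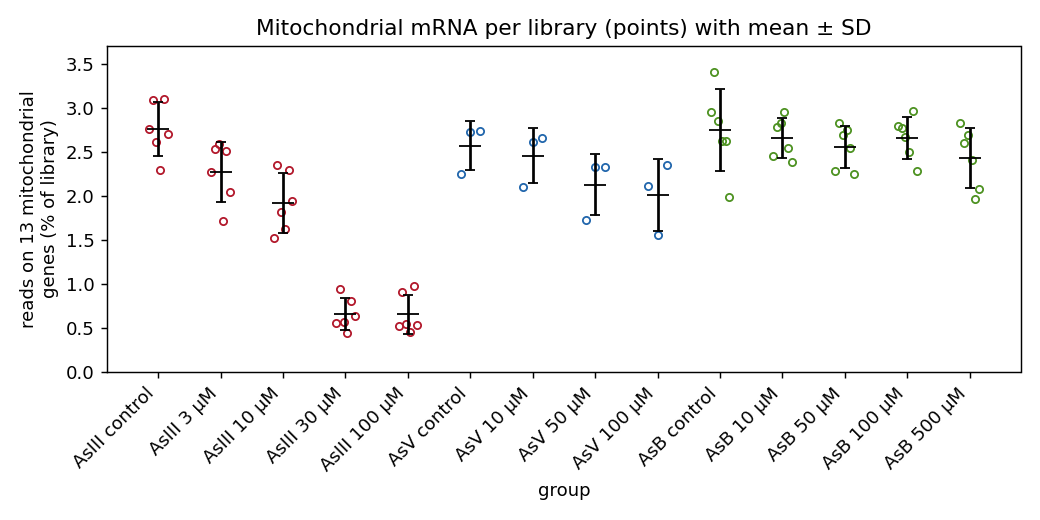
Share of reads in the 13 mitochondrially encoded mRNAs, in percent, per library, by group. AsIII libraries averaged 2.76% in the controls, 0.656% at 30 µM and 0.652% at 100 µM, and AsV libraries 2.00% at 100 µM.

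At 50 and 100 µM AsV, the genes that rose included members of the redox, heat shock and proteasome lists, and those that fell included members of the fatty acid synthesis list. The cystine/glutamate transporter-like gene LOC106604686 rose by 2.98 ± 0.29 at 50 µM and 2.81 ± 0.29 at 100 µM, the glutathione synthesis gene gsh1 by 1.81 ± 0.28 and 1.67 ± 0.28, and sqstm1 by 3.19 ± 0.44 and 3.24 ± 0.44 (n = 3). The S-adenosylmethionine synthase-like gene LOC106580346 stood at 52072 ± 15733 normalized counts at 50 µM against 4478 ± 1708 in the controls (3.57 ± 0.35). The greatest rises at 100 µM included the galanin-like gene LOC106573616 (7.19 ± 0.61, adjusted p = 9.41e-05), the organic anion transporter-like gene LOC106589510 (5.97 ± 0.97) and hs90a (5.30 ± 0.91). The cornichon-like gene LOC106563472 was listed at 0 in all AsV controls and averaged 821 ± 677 normalized counts. Falls at 100 µM included the acyl-CoA ligase 1-like gene LOC106612015, which averaged 5 ± 8.66 normalized counts with libraries at 0 among them, against 320 ± 130 in the controls. Others were the Wnt-9a-like gene LOC106599874 (-4.16 ± 0.64) and the aldolase B-like gene LOC106604855 (-3.09 ± 0.58).

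Of 67 redox genes, 20 rose and 1 fell at 50 µM and 19 and 1 at 100 µM (23 and 1, and 24 and 2, adjusted over the list alone). The camera adjusted p was 3.63e-08 and 3.99e-07 (adjusted p = 0.412 and 0.481 with an estimated correlation). The heat shock list gave 19 rises and 0 falls at 50 µM and 20 and 0 at 100 µM (30 and 34 rises adjusted over the list alone). Its medians were 1.51 and 1.98, with camera adjusted p of 8.59e-15 and 8.5e-17 (adjusted p = 0.669 and 0.577 with an estimated correlation). The hsp70 copy LOC106572869 varied between fish, at 1901 ± 1910 normalized counts at 100 µM against 38 ± 45.1, and its change of 5.63 ± 2.39 was not past the threshold. Of 69 proteasome genes 11 rose at 50 µM and 7 at 100 µM, with 0 falls (limma, 31 and 14 rises adjusted over the list alone, camera adjusted p = 4e-11 and 4.4e-08, adjusted p = 0.879 and 0.996 with an estimated correlation). Integrated stress genes gave 12 rises and 1 fall at both doses (19 rises adjusted over the list alone at both, with 2 falls and 1, camera adjusted p = 8.74e-06 and 7.79e-06, adjusted p = 0.996 with an estimated correlation at both). In this list chac1 stood at 3.41 ± 0.48 and 3.24 ± 0.48. Fatty acid synthesis genes gave 0 rises and 4 falls of 28 at both doses (8 and 5 falls adjusted over the list alone, camera adjusted p = 0.000226 and 0.00174, adjusted p = 0.76 and 0.873 with an estimated correlation). Those that fell included the dgat2-like gene LOC106603538 (-1.81 ± 0.36 and -1.90 ± 0.36) and gpam (-1.33 ± 0.28 and -1.23 ± 0.28), both of triglyceride synthesis. Of 48 p53 and cell death genes 8 rose and 5 fell at both doses (15 and 8, and 16 and 9, adjusted over the list alone, camera adjusted p = 0.0189 and 0.0212, adjusted p = 0.996 with an estimated correlation at both). Of 72 hepatocyte product genes 4 fell and 0 rose at both doses (camera adjusted p = 0.0205 and 0.0126, adjusted p = 0.996 with an estimated correlation). They included the HNF4α-like gene LOC106567096 (-1.65 ± 0.21 and -1.45 ± 0.21). The gluconeogenic gene pck1 fell by 2.42 ± 0.53 and 2.83 ± 0.53. The carbohydrate list gave 7 and 5 falls of 40 (7 at both adjusted over the list alone, camera adjusted p = 0.17 and 0.0216, adjusted p = 0.978 with an estimated correlation at 100 µM). Of 181 ribosomal protein genes 1 rose and 0 fell at both doses (limma, 1 and 0 rises adjusted over the list alone, medians 0.27 and 0.14, camera adjusted p = 7.94e-06 and 0.046, adjusted p = 0.996 with an estimated correlation at both). The metallothionein mtb rose at 50 µM (1.72 ± 0.44), and its change of 1.51 ± 0.44 at 100 µM passed the threshold with the block only. Of the 13 mitochondrial genes 3 fell at 50 µM and 2 at 100 µM (4 at 100 µM with the block), with ND4L at -1.90 ± 0.34 and -1.39 ± 0.34.

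Counts for AsV were 1077 rises and 698 falls at 50 µM and 1139 and 562 at 100 µM, of 25465 genes. The counts depended on the fish used. Leaving out fish 1, 2 or 3 gave counts equal to 9.52%, 24.5% and 23.6% of the 1775 at 50 µM, and 70, 149 and 2631 calls at 100 µM. The AsV dose libraries of fish 3 had 1069 to 1729 genes at 0. At 10 µM AsV, 0 genes passed with limma, where 116 had an unadjusted p below 0.05, edgeR called 0 and DESeq2 called 2. Those were the galanin-like gene LOC106573616 and the aldose reductase-like gene LOC106609239, named after their values were seen. Camera called 6 lists at 10 µM with 0 members past the threshold, among them the redox genes (median 0.08, adjusted p = 0.000504, and 0.854 with an estimated correlation) and cholesterol synthesis (-0.16, adjusted p = 5.63e-05, and 0.763 with an estimated correlation). The others were integrated stress (-0.13, adjusted p = 0.0212), proteasome (0.09, adjusted p = 0.0278), oxidative phosphorylation (0.06, adjusted p = 0.0304) and ribosomal protein genes (0.07, adjusted p = 0.000226), each at an adjusted p = 0.996 with an estimated correlation. Fatty acid synthesis was called with the block only (median -0.15, adjusted p = 0.0662, 0.0327 with the block, and adjusted p = 0.996 with an estimated correlation). The median 95% interval at 10 µM reached 0.84 to either side.

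**Figure D4:**
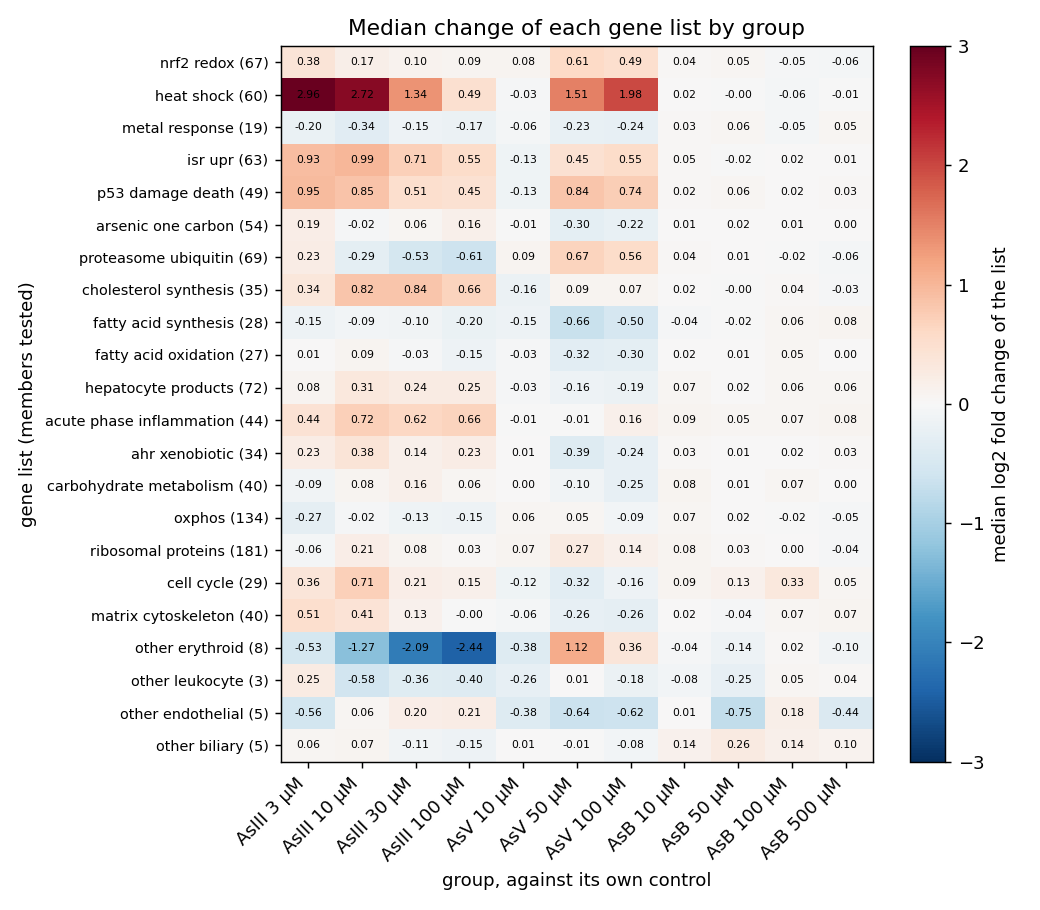
Median log2 fold change of the genes of each list (rows) in each dose group (columns), on a colour scale. The heat shock list had medians of 2.96 at 3 µM and 0.49 at 100 µM AsIII and of 1.98 at 100 µM AsV.

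AsB gave no gene past the threshold at 10, 50, 100 or 500 µM. With limma 0 of 25492 genes passed at each dose, where 790, 542, 715 and 848 had an unadjusted p below 0.05. The count was 0, 1, 0 and 0 with edgeR and 2, 1, 0 and 2 with DESeq2. None of the 36 copies of the stress and liver genes passed at any AsB dose, and at 500 µM 17 genes passed with the fish block. Among these 17, named after their values were seen, were complement C3-like LOC106569365 (0.19 ± 0.04), complement factor B-like LOC106563698 (0.20 ± 0.04), complement factor H-like LOC106595673 (0.22 ± 0.04), betaine-homocysteine methyltransferase-like LOC106568115 (0.23 ± 0.05) and aldose reductase-like LOC106609239 (-0.47 ± 0.08). The greatest changes of the 17 were those of crabp2 (4.67 ± 1.02) and the rho-related BTB domain gene LOC106580155 (1.23 ± 0.25). The 1 edgeR call at 50 µM was the alpha-mannosidase 2C1-like gene LOC106594313, also named after its values were seen. Camera called 8 lists at AsB doses, each with 0 members past the threshold of limma. At 10 µM these were the hepatocyte products (median 0.07, adjusted p = 0.0109), nuclear oxidative phosphorylation genes (0.07, adjusted p = 0.0044) and ribosomal proteins (0.08, adjusted p = 5.37e-09), and at 50 µM the ribosomal proteins (0.03, adjusted p = 0.0304). At 500 µM they were the hepatocyte products (0.06, adjusted p = 0.0154), acute phase genes (0.08, adjusted p = 0.0494), oxidative phosphorylation genes (-0.05, adjusted p = 0.027) and ribosomal proteins (-0.04, adjusted p = 0.00131). None of the 8 was called with an estimated correlation (adjusted p = 0.978 for the acute phase genes and 0.996 for the others). With the fish block 12 more lists were called, again with 0 members past the threshold of limma. None of the 12 was called with an estimated correlation, which was used without the block and so does not recheck the blocked calls. The biliary markers were called with the block at 10, 50 and 100 µM (medians 0.14, 0.26 and 0.14, adjusted p = 0.0396, 0.0382 and 0.017 with the block, and adjusted p = 0.978, 0.827 and 0.697 with an estimated correlation). The others each had an adjusted p = 0.996 with an estimated correlation. They were acute phase genes at 10 and 100 µM (medians 0.09 and 0.07, adjusted p = 0.00118 and 0.0106 with the block) and redox genes at 50 and 500 µM (0.05 and -0.06, adjusted p = 0.0148 and 0.019). Carbohydrate genes were called at 10 µM (0.08, adjusted p = 0.000623) and proteasome genes at 500 µM (-0.06, adjusted p = 0.00659). At 100 µM the remaining lists were heat shock (-0.06, adjusted p = 0.0382), cholesterol synthesis (0.04, adjusted p = 0.0276) and hepatocyte genes (0.06 with a mean of -0.05, adjusted p = 0.00018). The median 95% interval of a gene reached 0.64 to either side, and 55.6% of genes at 500 µM had an interval within 1 of 0. For the rest a change above 1 was not excluded.

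Responses were compared between compounds at matched doses. At 10 µM the response to AsIII exceeded that to AsB in 2999 genes and fell short of it in 2165 (1975 and 4120 under library-size scaling), and at 100 µM in 1888 and 1520 (1580 and 1628 under library-size scaling, 5470 in all with the fish block). The heat shock list gave 36 higher and 0 lower genes of 60 at 10 µM (limma, 42 and 0 adjusted over the list alone, median difference 2.55, adjusted p = 0.0239 with an estimated correlation). LOC106572869 differed by 9.0 (95% interval 5.38 to 12.61). At 100 µM, LOC106607825 differed by 3.37 (2.57 to 4.17). Acute phase genes were higher in AsIII in 13 cases and lower in 1 (18 and 1 adjusted over the list alone, median 0.65, adjusted p = 0.0306 with an estimated correlation), and 32 proteasome genes were lower (35 adjusted over the list alone, median -0.63, adjusted p = 0.302 with an estimated correlation). For gsh0 the difference at 100 µM was 0.19 (-0.25 to 0.64) and was not past the threshold.

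The responses to the 2 inorganic forms differed at both matched doses. At 10 µM, 1793 genes were higher and 966 lower in the response to AsIII than in that to AsV (1151 and 2600 under library-size scaling, 4659 in all with the block). There 36 of 60 heat shock genes were higher and 0 lower (38 and 0 adjusted over the list alone, median 2.66, adjusted p = 0.0239 with an estimated correlation), and sqstm1 differed by 3.11 (2.46 to 3.76). Of 63 integrated stress genes, 26 were higher and 0 lower (limma, 38 and 0 adjusted over the list alone, median 1.18, adjusted p = 0.0306 with an estimated correlation). At 100 µM, 1762 were higher and 1879 lower (5521 in all with the block). There 42 of 69 proteasome genes were lower in the AsIII response and 0 higher (43 and 0 adjusted over the list alone, median -1.15, adjusted p = 0.0396 with an estimated correlation). Of 67 redox genes, 20 were lower and 2 higher (24 and 2 adjusted over the list alone, median -0.54, adjusted p = 0.0306 with an estimated correlation). The difference was -3.50 for sqstm1 (-4.15 to -2.84), -1.39 for the thioredoxin reductase copy LOC106565239 (-1.74 to -1.05), -1.18 for gsh1 (-1.72 to -0.64) and 1.72 for LOC106607825 (0.74 to 2.70). Leaving out fish 1, 2 or 3 lowered the 10 µM count of 2759 to 1784, 1733 and 1500, and leaving out fish 2 lowered the 100 µM count of 3641 to 2072.

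AsV and AsB differed in 1332 genes higher and 1138 lower at 50 µM (1029 and 1329 under library-size scaling, 4220 in all with the block) and in 1501 and 1026 at 100 µM (4259 with the block). The redox list gave 21 higher genes and 1 lower at both doses (24 and 1, and 27 and 3, adjusted over the list alone, medians 0.45 and 0.47, adjusted p = 0.0239 with an estimated correlation at both). Of 60 heat shock genes, 30 were higher at 100 µM (40 adjusted over the list alone, median 1.72, adjusted p = 0.0306 with an estimated correlation). The gsh1 difference was 1.76 (1.22 to 2.30) at 50 µM. At 10 µM, 0 genes passed with limma and 497 had an unadjusted p below 0.05, while edgeR called 0 and DESeq2 called 0. The median 95% interval there reached 0.98 to either side. Without fish 3 the 50 µM count was 777, and without fish 1 or 2 the 100 µM count was 1168 or 1116.

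The control groups of the 3 compounds, which carry no arsenic, gave 0 genes past the threshold in each pairing with limma. An unadjusted p below 0.05 was met by 4.12% of genes for AsIII against AsB controls, 0.635% for AsIII against AsV and 4.04% for AsV against AsB. In these pairings edgeR called 0 in each and DESeq2 called 4, 0 and 2. The block gave 2 genes for AsIII against AsB controls. Camera called lists between controls as well, with the ribosomal proteins at a median of -0.23 in AsV against AsB controls (adjusted p = 3.77e-55, and adjusted p = 0.323 with an estimated correlation). This was a larger shift than those of the lists called for AsB doses without the fish block.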

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

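Of the tests below, those of the scaling, of swapped libraries, of reversed labels, of exchanged labels, of thinned AsV libraries, of a weak AsV response, of a rise of other transcripts and of respiratory chain mRNA were chosen only after the result was seen.

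Dixon's test was run on 30 library measures and 312 changes of named genes in groups of 6 fish, and chance alone picks out about 1 in 20. It picked out 4 library measures. At 10 µM AsIII, fish 4 had 86.42 M reads, where the other fish had 30.92 to 39.44 M. At 30 µM AsIII, fish 5 had 1396 genes at 0, where the others had at most 270. At 100 µM AsIII, fish 1 had 42.9 M reads, where the others had 32.24 to 35.33 M, and 1694 genes at 0, where the others had 193 to 298.

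The test also picked out 9 gene changes, each a log2 fold change of 1 fish against its own control. The metallothionein mta (LOC100136589) was at 0.8937 in fish 2 at 10 µM AsIII, above the 0.2826 to 0.4838 of the other fish. In fish 1 at 100 µM AsIII, the thioredoxin reductase 1-like gene LOC106609375 was at 5.385 (others 0.168 to 2.052) and fam20a at -8.022 (others -3.223 to -2.452). In fish 5 at 30 µM AsIII, the sialyltransferase-like gene LOC106570212 was at -0.7247, where the others were at -3.81 to -2.939. Among AsB libraries, the arsenite methyltransferase-like gene LOC106588782 was at -0.2313 in fish 5 at 10 µM (others 0.07227 to 0.1616). At 50 µM AsB, the heme oxygenase-like gene LOC106590030 was at 0.784 in fish 4 (others -0.09119 to 0.166), hsp70-3 at 5.429 in fish 6 (others -0.1728 to 1.885) and alb1 at 0.1893 in fish 1 (others -0.08648 to 0.01265). At 500 µM AsB, the hsp70-like gene LOC106607232 was at 2.301 in fish 3 (others -0.9228 to 0.2746).

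Against the same AsIII controls, 7132 genes were past the threshold with an absolute log2 change of at least 1 at 3 µM and 3634 at 100 µM, a ratio of 1.96 between 2 counts. Library depth as the whole cause of this ratio is argued against by libraries thinned to 30.9 M reads, which gave 7110 and 3614 genes and a ratio of 1.97, and the authors' scaling by a lowest ratio of 1.99 under 2 other scalings. Swapped libraries in some fish met the bound first stated for them, since the root mean square change was larger at 3 than at 100 µM in 5 of 6 fish but not in fish 1 (1.28 against 1.46, with 1694 genes at 0), yet the score of each fish along the AsIII 3 µM change of other fish, a test added after that result, fell at each dose step in 6 of 6 fish, which argues against such swaps. Dose labels reversed in every fish stay open, because the same order in 6 of 6 fish would follow from them. An early stop of transcription at 100 µM also stays open, as 87.3% of 9310 genes that differed between 3 and 100 µM in fish 4 to 6 moved toward the control, a share between the bounds set beforehand, although 47.3% of them lay on the other side of the control in fish 1 to 3.

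The AsV 100 µM library of fish 3 stood apart, with a score of 0.192 along the AsIII 3 µM change of fish 4 to 6 against 0.676 and 0.604 in fish 1 and 2. A weak AsV response of fish 3 is argued against by its 50 µM library, which scored 0.723 against 0.365 and 0.251. Low depth met the test stated beforehand, since the library had 31.8 M reads, the fewest of the AsV libraries (median 38.9 M). A test chosen afterwards argues against low depth or few genes detected as the whole cause, because over 4203 genes with a mean of at least 1000, with libraries thinned to those reads, fish 3 scored 0.337 against 0.739 and 0.748, a ratio of 0.456 close to its bound of 0.5. An exchange of the 50 and 100 µM labels of fish 3 stays open as a hypothesis that could account for both scores of this fish, and all values here use the labels as given.

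Of the 13 mitochondrial genes, 6, 8, 12 and 12 fell at 3, 10, 30 and 100 µM AsIII and 3 and 2 at 50 and 100 µM AsV, and the explanations were tested at 100 µM AsIII, where the median log2 change was -2.26, or -2.34 under library-size scaling. A rise of some other transcripts as the whole cause is argued against by that median in normalized values. A general rise of other mRNA per cell was not tested, because both scalings are relative and would give the same values. A fall of few genes is argued against by the 12 genes that were lower (13 with the fish block). Loss of all respiratory chain mRNA is argued against by the nuclear genes of the chain, whose median was -0.148, with 32 falls and 12 rises among 134. A selective loss of mitochondrial transcripts may be set beside these values as a hypothesis, and weaker capture of these mRNAs in the libraries was not tested.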

How the results depend on the processing

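TMM scaling with limma and pseudocounts of 0.5 and 10 were tests chosen only after the result was seen. So were the filter on a mean of at least 100 and the edgeR fits with TMM on recovered reads. The plan fixed beforehand had named edgeR with TMM on raw read counts as the main test. The other edgeR fits and DESeq2 on recovered reads were set up once the values proved to be normalized. The remaining alternatives were fixed before the data were examined. Counts below are genes past the threshold, and any combination of count and alternative not given here stayed within 1.5 times of its reported value.

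Asking for an absolute log2 change of at least 1, which counts fewer genes by construction, gave 7132, 5079, 3893 and 3634 genes at 3, 10, 30 and 100 µM AsIII, 2032, 1821 and 225 for the steps from 3 to 10, 10 to 30 and 30 to 100 µM, and 3204 and 1865 for AsIII against AsB at 10 and 100 µM. All 72 libraries in one fit gave 7040 and 6642 at 30 and 100 µM AsIII, 4347, 2928 and 1.7e+02 for the steps, 3915 and 3666 at 50 and 100 µM AsV, and 11, 1, 1 and 3 at 10, 50, 100 and 500 µM AsB. Only the 2 groups compared gave 274 for the step from 30 to 100 µM. DESeq2 gave 2, 3253 and 3292 at 10, 50 and 100 µM AsV, 2, 1 and 2 at 10, 50 and 500 µM AsB, and 4 and 2 for AsIII and AsV controls against AsB controls. At 50 µM AsB edgeR gave 1 with either scaling. Fits of only the libraries compared gave 6357 for AsIII against AsV at 10 µM, 1448 and 1179 for AsV against AsB at 50 and 100 µM and 2 for AsIII against AsB controls. Fish 1 to 3 only, which leaves fewer libraries, gave 1539, 1450 and 1346 for the same responses and 1 for AsV against AsB controls. The cause was not tested for these shifts apart from those set by construction.

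With fish as a replicate block, a count moved past 1.5 times for the step from 30 to 100 µM (904), 500 µM AsB (17), AsIII against AsB at 100 µM (5470), AsIII against AsV at 10 and 100 µM (4659 and 5521), AsV against AsB at 50 and 100 µM (4220 and 4259) and AsIII against AsB controls (2). The block with edgeR and TMM gave 8492 and 1115 for the steps from 10 to 30 and 30 to 100 µM, 2770 and 2882 at 50 and 100 µM AsV, 1, 1 and 33 at 10, 50 and 500 µM AsB, 8057 and 6322 for AsIII against AsB, 5303 and 6079 for AsIII against AsV, 4604 and 5040 for AsV against AsB at 50 and 100 µM, and 1 for AsIII against AsB controls. Of the 242 list tests, 27 were called with the block only, all given with their lists, and the pairing changed no other call of a list at a dose. Among values of named genes, 22 newly passed the threshold with the block and 3 no longer did.

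Of 15183 values of named genes under alternatives, 14628 kept their direction and side of the threshold, 146 newly passed it, 407 no longer did and 2 reversed. The reversed ones were alb1 (-0.0263) and LOC100136922 (-0.0143) at 3 µM AsIII, both under library-size scaling, which moved the median of all genes down. TMM scaling turned small majorities of rises to falls, with 7070 and 7174 at 3 µM, 6062 and 6179 at 10 µM and 5155 and 5411 at 100 µM AsIII, and with 2611 and 2688 at 10 µM and 1675 and 1820 at 100 µM for AsIII against AsB. Of the list calls at doses, 57 with the preset correlation became 0 with an estimated one and 84 with the block, while fry lost 28 of them and added 26. Calls of cell-type marker lists went from 5 to 0 with an estimated correlation, 15 with the block and 8 with fry.

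Leaving out each fish in turn gave 12704 to 13629, 10836 to 11468, 9108 to 10173 and 8683 to 9579 genes at the AsIII doses, and 6323 to 7025, 4113 to 5101 and 317 to 366 for the steps. The range was 0 to 0, 1.7e+02 to 435 and 70 to 2631 at 10, 50 and 100 µM AsV, where 2 libraries per group remained and the lowest counts came without fish 1. It was 0 to 0 at every AsB dose with limma. For responses it was 4021 to 4331 and 2434 to 2882 (AsIII against AsB), 1500 to 2567 and 2072 to 3462 (AsIII against AsV), and 0 to 0, 777 to 2497 and 1116 to 2643 (AsV against AsB). Between controls it was 0 to 1, 0 to 0 and 0 to 2, the calls coming without fish 4 and without fish 2. The median 95% interval of a gene reached 0.43 to either side for AsIII and 0.64 for AsB, both with 6 fish, and 0.84 for AsV with 3 fish, and the cause was not tested.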

Other observations

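The vitellogenin values were taken up, and the AsB genes of this part named, only after the result was seen, and the other tests of this part were fixed before it.

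Genes of further lists changed under AsIII. Their counts are to be read against those over all 25801 genes tested. Of these, 7621 rose and 6453 fell at 3 µM and 6906 and 5283 at 10 µM. At 30 µM the counts were 6170 and 4557, and at 100 µM 5831 and 4475. At 3 µM the methionine synthase-like gene LOC106593539 rose by 3.99 ± 0.16, mtr by 2.65 ± 0.16 and the S-adenosylmethionine synthase-like gene LOC106580346 by 1.75 ± 0.28, and the 54 genes of arsenic and 1-carbon metabolism gave 19 rises and 17 falls (22 and 17 adjusted over the list alone), then 17 and 12, 13 and 12, and 14 and 15 at the higher doses. The connective tissue growth factor-like gene LOC106572617 rose by 5.47 ± 0.41 at 3 µM and 6.28 ± 0.41 at 10 µM, and the matrix list gave 17 rises and 2 falls of 40 and 16 and 2 (17 and 1, and 15 and 2, adjusted over the list alone), called with the fish block only (camera adjusted p = 0.0621 and 0.116, 0.0151 and 0.0278 with the block, and adjusted p = 0.996 with an estimated correlation at both). It gave 11 rises and 4 falls at both 30 and 100 µM. Perilipin-2 (plin2), a lipid droplet coat protein, rose by 2.51 ± 0.22 at 3 µM, in a list of fatty acid oxidation genes with 7 rises and 6 falls of 27. The ribonucleotide reductase subunit rrm2, of DNA synthesis, rose by 5.35 ± 0.59 at 3 µM and 2.01 ± 0.59 at 100 µM, and 6 of 29 cell cycle genes rose and 2 fell at 3 µM (5 and 2 adjusted over the list alone). The low-density lipoprotein receptor-like gene LOC106601326 fell by 2.99 ± 0.13, while cholesterol synthesis genes gave 12 rises and 4 falls of 35 (11 and 4 adjusted over the list alone).

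The 72 hepatocyte products gave 12 rises and 13 falls at 3 µM (9 and 13 adjusted over the list alone), with a median of 0.08 and a mean of 0.06 where the list test pointed down, and HNF4α-like LOC106567096 and fibrinogen alpha-like LOC106608432 each fell by 1.09. At 10, 30 and 100 µM there were 31, 28 and 25 rises and 6, 4 and 4 falls, called with the block only (camera adjusted p = 0.0661, 0.164 and 0.0662, 0.000899, 0.00989 and 0.00222 with the block, and adjusted p = 0.996 with an estimated correlation at each). The gluconeogenic gene pck1 fell by 2.89 ± 0.48 at 3 µM, with 15 falls and 5 rises of 40 carbohydrate genes, and the glucokinase-like gene LOC106585167 rose by 2.11 ± 0.23 at 30 µM. Aryl hydrocarbon receptor targets gave 17 rises and 4 falls of 34 at 10 µM, called with the block only (camera adjusted p = 0.0826, 0.0152 with the block, and adjusted p = 0.996 with an estimated correlation), led by LOC106606453, a cytochrome P450 2K1-like gene (2.54 ± 0.24). At 50 µM AsV the same list had 2 rises and 1 fall (2 and 2 adjusted over the list alone, camera adjusted p = 0.216, 0.0481 with the block, and adjusted p = 0.996 with an estimated correlation), the rises being gsta (2.47 ± 0.31) and LOC106613254 (1.41 ± 0.39). The cyp1a copies went the other way where responses were compared with those to AsB. At 10 µM AsIII the differences were -1.27 and -1.54 (limma adjusted p = 0.0349 and 0.0286). At 50 µM AsV they were -1.94 and -2.61 (limma adjusted p = 0.0134 and 0.00396). Zinc transporter 1-like LOC106571198 fell by 1.98 ± 0.24 at 50 µM AsV, among 2 falls and 1 rise of 19 metal response genes. Markers of other cells were few. At 30 µM AsIII, 4 of 8 erythroid genes fell and 0 rose with limma (camera adjusted p = 0.0839, 0.0279 with the block, and adjusted p = 0.996 with an estimated correlation), 1 of 3 leukocyte, 2 of 5 endothelial and 1 of 5 biliary markers fell, and none of the last 3 lists was called at an AsIII dose. At 3 µM the erythroid median was -0.53 and the mean 0.45.

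Among calls made by some settings at AsB doses, the alpha-mannosidase 2C1-like gene LOC106594313 was at 3.13 at 50 µM with edgeR (adjusted p = 0.0382) and 2.77 at 10 µM with DESeq2 (adjusted p = 0.0495). DESeq2 also called sepsecs at 10 µM (0.87, adjusted p = 0.00671) and crabp2 (7.48, adjusted p = 0.00169) and the kelch-like gene LOC106572566 (-1.75, adjusted p = 0.00784) at 500 µM. With all libraries in one fit, the SHC-like gene LOC106593005 was called at 100 µM (-2.76, adjusted p = 0.0332) and the uncharacterized LOC106574991 at 500 µM (-1.73, adjusted p = 0.0255). That limma fit also called LOC106594313 at 50 µM (3.69, adjusted p = 0.00123). At 500 µM it called crabp2 (4.67, adjusted p = 0.000335) and LOC106572566 (-1.71, adjusted p = 0.0319) as well.

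Vitellogenin (LOC100136426), a yolk precursor made by the liver under estrogen, ranked 16 or better among all genes in every control library, although the labels give the fish as male. It stood at 487436 ± 209587, 447226 ± 223674 and 547257 ± 246640 normalized counts in the AsIII, AsV and AsB controls. At 3 µM AsIII it stood at 62446 ± 50159 and had fallen by 3.24 (adjusted p = 8.62e-05). Its AsV changes were not past the threshold (-2.64 at 50 µM and -3.03 at 100 µM), and single AsV 100 µM libraries lay between 13982 and 378383.

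The hypothesis that AsV at 100 µM resembles AsIII at 3 µM more than AsIII at 100 µM was tested with correlations of log2 changes across 25442 genes, which are not independent replicates. Pearson's r was 0.696 with AsIII at 3 µM and 0.225 at 100 µM, a difference of 0.471, and Spearman's rho was 0.657 and 0.191. The compounds share no control library, but fish 1 to 3 are common to both. The values are consistent with the hypothesis and with a lower effective dose of AsV, which was not tested.

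Other groupings of the libraries compared were run through the same test, fitted to those libraries alone. For AsIII against control, 1 of 100 groupings, the real one, gave as many genes at each dose, a share below 0.05. It gave 14854, 13059, 10184 and 9695 genes where the highest other gave 8, 6, 392 and 9. The other groupings mix dosed and control libraries, which widens the spread within groups and lowers their counts. Only 4 of them parted as many pairs of fish, too few for a share below 0.05 with the pairing kept. With the same limits, only the real grouping gave as many for the steps from 3 to 10 µM (8474, highest other 29) and 10 to 30 µM (4865 and 37). For the step from 30 to 100 µM, 2 of 100 groupings gave as many, and the other of these 2 gave more genes than the real one (485 against 274). The 4 other groupings that parted as many pairs of fish gave at most 0 genes, but are too few for a share below 0.05. Chance is therefore not called excluded for this step or for the other AsIII comparisons. Between compounds, the real and the highest other grouping gave 5708 and 0 genes for AsIII against AsB at 10 µM and 3398 and 0 at 100 µM. The counts were 6357 and 0 for AsIII against AsV at 10 µM and 4766 and 3 at 100 µM. For AsV against AsB they were 1448 and 4 at 50 µM and 1179 and 0 at 100 µM. In each of these differences only the real grouping gave as many, 1 of 100 or of 84. The other groupings that parted as many pairs of fish numbered 4 for AsIII against AsB and 7 for the differences with AsV. These are too few for a share below 0.05 with the pairing kept, so chance is not called excluded here either. For AsV the 10 groupings of 6 libraries cannot give a share below 0.1, and the real ones gave 0, 2250 and 1139 genes where the highest other gave 0. Where the real count was 0, every grouping gives as many by construction, and nothing about chance follows. This holds for the AsB doses (100 of 100, highest other 306, 123, 496 and 415), for AsV against AsB at 10 µM (84 of 84, highest other 0) and for AsIII against AsV controls (84 of 84, highest other 113) and AsV against AsB controls (84 of 84, highest other 233). For AsIII against AsB controls, 9 of 100 groupings gave as many (2, highest other 186), so that chance cannot be excluded. A structure of the samples by fish could lie behind groupings with many calls, but which libraries these put together was not examined. Groupings parting as many pairs of the same fish as the real one gave at most 0 genes, or 3 for AsIII against AsV at 100 µM.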
